A study of Bos taurus with 39 samples.

How the data were processed

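Milk somatic cells, the cells shed into milk, were collected from 39 Holstein cows through a cannula, and RNA extracted with Trizol was made into libraries with the TruSeq RNA kit, per the labels' protocols. The labels place 22 cows in a LOW RFI group and 17 in a HIGH RFI group. RFI is taken here as residual feed intake, the feed an animal eats beyond what its production and body weight predict, so that a low value stands for a more efficient animal. Each cow contributed 1 library, and the cows are the replicates. Numbers such as LOW RFI 14 are names in label order and pair no animals.

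The authors deposited 1 table of 21661 features in 39 columns of RPKM, reads scaled by gene length in kilobases and by the library's mapped reads, per the file headers. The genome build is ARS-UCD1.2, per the submitters' processing notes. The aligner, the counter and the annotation are not given in the sources used here. The reference table at hand is of another assembly of the cow, ARS-UCD2.0, and was used for names only, so no coordinates are given. Of the identifiers, 17331 matched a symbol in it, 68 matched only a synonym and 4017 were Ensembl identifiers without a symbol. Rows that share a symbol with another row (135) were summed, which left 21590 genes. Whether the counting used strand is not stated, so reads of overlapping or antisense genes cannot be separated, and near-identical gene copies may share reads.

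Because an RPKM value is a whole number of reads divided by gene length and library total, reads, lengths and totals were recovered from the ratios of low values. All 19616 features with a value above 0 gave whole reads within a tolerance of 0.02 reads. This share means little for features seen in few libraries, where some length always gives whole reads. The recovered library totals lay within 0.00145 of whole numbers. On 12000 simulated genes in 39 libraries, leaving out those with reads in few libraries, the recovery returned 100% of the reads. The recovered totals lie between 41637742 and 204905052 mapped reads, of which 80.9% to 96.5% fell in genes. The recovered gene lengths had a median of 2321 bp, and 37.8% were multiples of 3. The plan had named a count model for deposited counts and a test on log values for normalized values. As the table held RPKM, the latter was the test used, and the recovered reads entered only the alternatives with limma-voom.

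The test on genes was limma-trend (limma 3.58.1 in R 4.3.3, empirical Bayes with a trend and robust settings) on log2(RPKM + 1), with features of at least 1 RPKM in at least 17 cows, which kept 10636 genes. Differences are LOW RFI minus HIGH RFI on that log2 scale, and the pseudocount of 1 makes the difference of a low gene look smaller than it is. The threshold was a Benjamini-Hochberg adjusted p of 0.05. Recovery was tried with the residuals of the real cows shuffled and changes of several sizes inserted together into genes drawn at random. Limma-trend recovered 21.8% of genes changed by a log2 of 0.5, 78.8% at 1 and 98.6% at 2, with a median of 0 false calls and at most 2 in 10 draws. Gene lists (28, with 788 members in all, 27 of them with no row in the table) were tested with limma's camera, two-sided, with a preset correlation of 0.01, for the 27 lists with at least 5 tested members. camera asks whether a list stands apart from all other genes. With cows labelled at random, it called a median of 11 lists and up to 20, and 49 of 50 labellings gave a call. With an estimated correlation 8 of 50 labellings gave one. A list of 25 genes drawn at random and shifted by a log2 of 1 was found in 50 of 50 under both settings, at an unadjusted p under 0.05. Such genes lack the correlation within the real lists, estimated at 0.11 (milk fat synthesis) to 0.93 (mitochondrial genome). The 50 of 50 therefore does not show that a change of a real list would be found. Cell type scores are the mean log2(RPKM + 1) over the tested members of 8 of the lists, compared by a two-sided permutation test of group means with 100000 resamples.

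The lists, the tests, the alternatives and the rule for naming genes were fixed before the data were examined. The rule names all genes that pass or, with fewer than 10 passing, the 10 smallest unadjusted p in each direction with at most 2 Ensembl-only identifiers each, then for each list the 2 members of highest mean level where none passes, and the 5 features of highest mean level. Of the genes that the rule names, 1 is not reported here. Genes named outside it were chosen after their values were seen. The alternatives were other scalings, filters, pseudocounts and thresholds, cell type scores or library number as covariates, libraries left out, limma-voom with quality weights on the recovered reads, camera with an estimated correlation, and fry. Added after seeing the data were fits with a month tag, without the libraries that carry a mark, with residual components, with array weights, with limma-voom without quality weights, with a gene length trend removed and with centred libraries. Also added were the values of named genes without the cow in which each is highest, and the correlations of the cell cycle score with the score of each of the 27 other lists. The file headers carry a month and year in each column name, from September 2019 to June 2020, and in 8 of them, 7 of 22 LOW RFI and 1 of 17 HIGH RFI cows, a further mark after the animal number (Fisher's exact p = 0.106). The column name of LOW RFI 3 has another mark, after the month and year, and that library was kept in every fit that left out marked libraries. None of these is explained in the sources used here. No 2 libraries were duplicates, the largest Pearson correlation between a pair being 0.991 with 0.00607% of values above 0 equal. Figures were drawn with Python 3.11.15.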

Results

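Transcript levels were measured in milk somatic cells of 39 Holstein cows ranked by feed efficiency, 22 labelled LOW RFI and 17 labelled HIGH RFI, where RFI is taken as residual feed intake. The series asks which genes differ between these extremes. Mapped reads per library had a mean of 98433353 ± 37938354 (SD, n = 22) in LOW RFI and 95941846 ± 22589134 (SD, n = 17) in HIGH RFI cows, and the difference of 2491506 reads was within the spread between cows (two-sided permutation p = 0.818). The shallowest library, LOW RFI 14, held 41637742 mapped reads. At these depths a median of 182 to 5794 reads lay behind each of the 10 genes named below with the smallest p among those higher in LOW RFI. Features at 1 RPKM or more numbered 10036 ± 769 (SD, n = 22) and 10243 ± 1095 (SD, n = 17).

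Milk protein transcripts were the most abundant RNA in these cells. The 5 features of highest mean level were CSN2 (beta-casein), PAEP (beta-lactoglobulin), CSN1S1 (alpha-s1-casein), CSN3 (kappa-casein) and CSN1S2 (alpha-s2-casein). CSN2 was at 53595 ± 49591 RPKM (SD, n = 22) in LOW RFI and 33732 ± 44614 RPKM (SD, n = 17) in HIGH RFI cows, a log2 difference of 0.96 with an SE of 0.77. The milk protein list took 27.6 ± 23.1% of all RPKM (SD, n = 22) in LOW RFI and 17.8 ± 20.5% (SD, n = 17) in HIGH RFI cows, and ranged from 0.117% to 80.4% over the cows. That difference was within the spread between cows (permutation p = 0.177). The log2 differences of PAEP, CSN1S1, CSN3 and CSN1S2 were 1.06, 1.08, 0.79 and 1.16, with unadjusted p between 0.157 and 0.301, so none passed.

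The cells differed widely between cows in the markers of their types, within both groups. Neutrophil markers had a mean score of 4.02 ± 1.41 (SD, n = 22) in LOW RFI and 4.88 ± 1.53 (SD, n = 17) in HIGH RFI cows, and 17 of 22 LOW RFI cows lay below the HIGH RFI median. The difference of -0.86 (SE 0.47) did not pass the permutation test (p = 0.0750, adjusted over 8 scores 0.497). Macrophage markers scored 5.62 ± 1.35 (SD, n = 22) and 6.04 ± 1.26 (SD, n = 17), a difference of -0.42 (permutation p = 0.329). For mammary epithelium, the secretory and duct lining, the difference was 0.24 (p = 0.373), and for milk protein it was 0.78 (p = 0.237). T cell markers differed by -0.17 (p = 0.627), NK and cytotoxic markers by -0.30 (p = 0.302), B and plasma cell markers by -0.25 (p = 0.149) and erythrocyte markers by 0.061 (p = 0.630), the last on 3 tested members. None of the 8 scores passed, and the smallest adjusted p was 0.497. The LOW RFI cows below the HIGH RFI median also numbered 17 for B and plasma cell markers. They numbered 16 for T cell, 16 for NK and cytotoxic and 15 for macrophage markers. For mammary epithelium, milk protein and erythrocyte markers they numbered 7, 8 and 10.

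The month in the column names was uneven between the groups, as all 6 cows tagged February 2020 were HIGH RFI. Months that hold 1 group only add nothing to a comparison adjusted for month, which rests on 19 LOW RFI and 9 HIGH RFI cows. Within the months that held at least 2 cows of each group, the neutrophil score differed by -1.05 in September 2019 (4 LOW RFI against 2 HIGH RFI cows, exact permutation p = 0.467), by 0.51 in January 2020 (2 against 2, exact p = 1) and by -0.11 in June 2020 (6 against 3, exact p = 0.929). With 4 cows against 2 the smallest possible exact p is 0.0667. With 2 against 2 each split has a mirror split of the same absolute difference, so the smallest two-sided exact p is 0.333. Those months could not pass. The milk protein score differed by 3.75, -0.96 and -1.03 in the same months (exact permutation p = 0.0667, 1 and 0.476). Adjusted for all months, the neutrophil difference was -0.17 and the milk protein difference 0.34. The June values lean on HIGH RFI 17, at 0.970 for neutrophil and 11.5 for milk protein. HIGH RFI 14 and HIGH RFI 16 were at 3.77 and 6.68 for neutrophil and at 9.78 and 9.32 for milk protein. The LOW RFI means in June were 3.70 and 9.18.

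**Figure D1:**
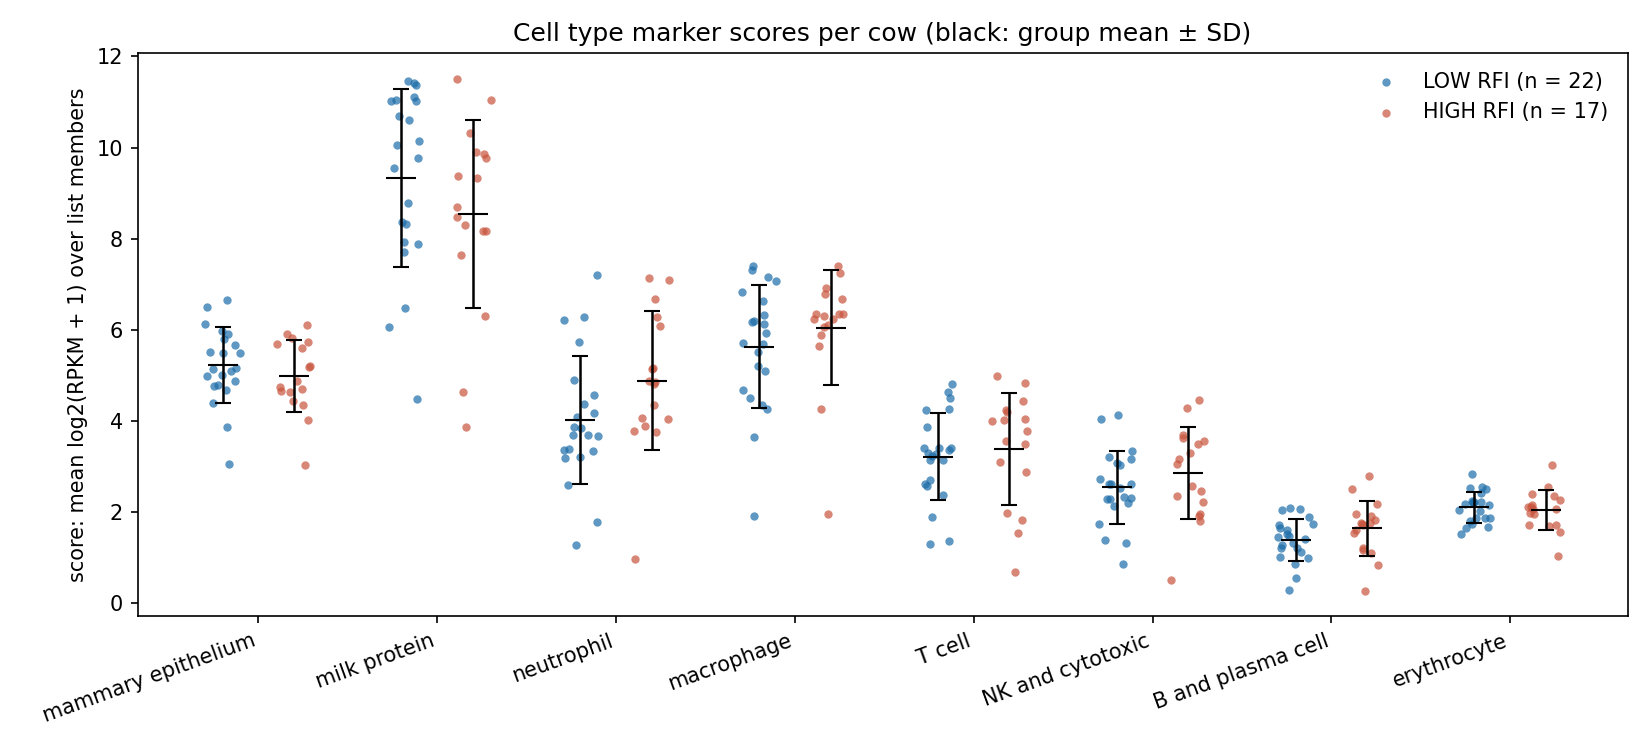
Cell type marker scores (mean log2(RPKM + 1) over list members, y axis) for 8 lists, with 1 point per cow, 22 LOW RFI cows in blue and 17 HIGH RFI cows in red, and black bars for the group mean ± SD. The milk protein score spans 3.86 to 11.5 over the cows and the neutrophil score 0.970 to 7.20, and the groups overlap in every list.

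Genes of these cell types lay at the ends of the first 2 principal components. The first component held 53.9% of the variance and set milk protein genes (CSN1S2, CSN1S1, LALBA) against macrophage and monocyte genes (CCL2, APOE, FCER1G), with mean loadings of the macrophage list (-0.0222) and the neutrophil list (-0.0197) about equal. The second held 12.0% and set inflammatory and neutrophil genes (PTX3, IL1B, CXCR1) against a negative end where S100A14, an epithelial gene, lay and where the mean loadings of the mammary epithelium list (-0.0210) and of the T cell list (-0.0209) were about equal, and the third, which set DDX3X and SMARCA5 against RPL12 and PAEP, held 8.68%. These example genes were chosen after their values were seen. Group means on the first 3 components differed by 22.6, -8.44 and 10.8 units (permutation p = 0.220, 0.333 and 0.141), within the spread between cows.

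**Figure D2:**
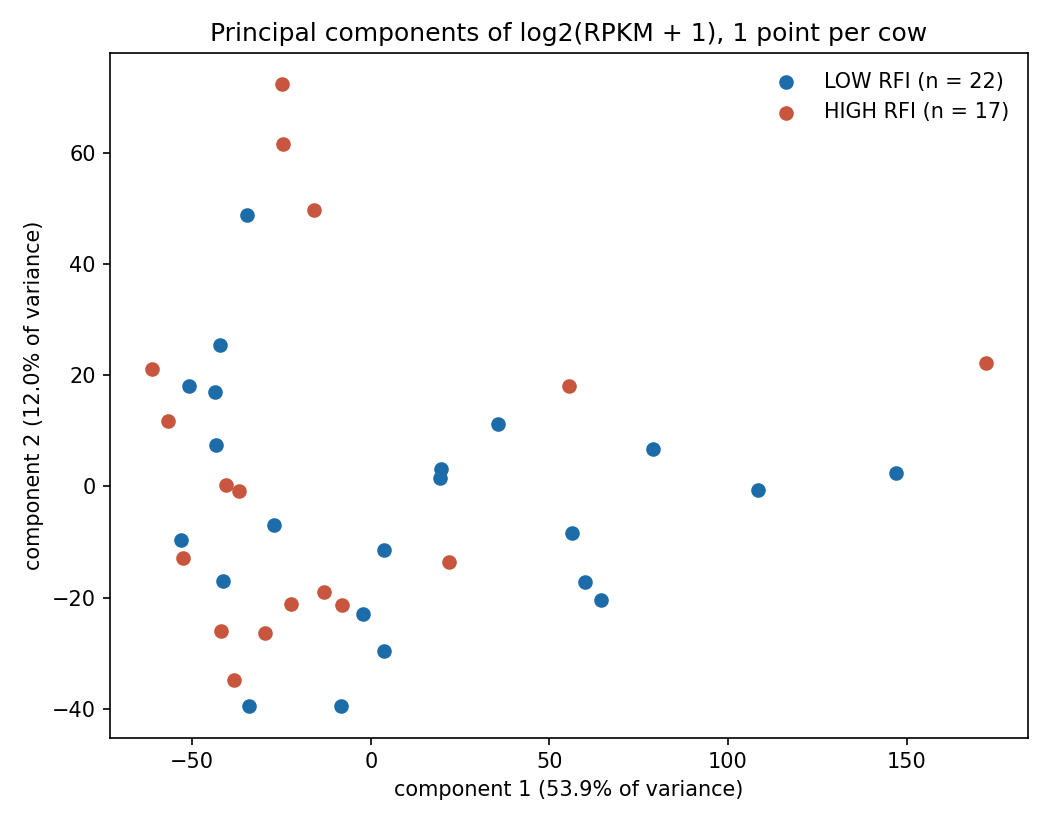
First (x axis, 53.9% of variance) and second (y axis, 12.0% of variance) principal components of log2(RPKM + 1), with 1 point per cow, 22 LOW RFI cows in blue and 17 HIGH RFI cows in red. Both groups spread along both components, with a difference of group means of 22.6 on the first (permutation p = 0.220).

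No single gene passed the test between LOW RFI and HIGH RFI cows. Of 10636 genes, 0 passed limma-trend at an adjusted p under 0.05, and the smallest adjusted p was 0.769. At an unadjusted p under 0.05 there were 633 genes, where 531.8 are expected by chance, and 587 of them (92.7%) were lower in LOW RFI. That expectation does not give the spread. Other splits of the cows into groups of 22 and 17 gave a median of 163 such genes and up to 4290. Of 100 splits, the real one included, 22 gave at least 633 genes. In 48 of the 100 the share in the commoner direction was at least 92.7%. The median difference of all genes was -0.12, and it moved to 0.017 with quantile normalization and to -0.024 with libraries rescaled without the milk protein list, so medians of the lists are also given relative to that of all genes. Among genes at an unadjusted p under 0.05, 7.27% were higher in LOW RFI as deposited, 48.5% with quantile normalization and 33.8% with that rescaling. Limma-voom on the recovered reads called 0 genes without quality weights and 1932 with them, 1919 of these lower in LOW RFI, and 0 with weights and the month tag together. Limma with array weights called 2213 genes, and with 2 residual principal components as covariates 1823, both chosen after seeing the data. Array weights with the month tag called 0, in a fit whose weights stopped short of convergence. Without the 8 libraries whose column name carries a mark after the animal number, 7 of them LOW RFI, limma-trend called 0, and 106 genes had an unadjusted p under 0.05. Without the 4 libraries that correlate least with the others (HIGH RFI 11, HIGH RFI 17, LOW RFI 18 and LOW RFI 20), limma-trend called 0, and 1048 genes had an unadjusted p under 0.05.

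The genes with the smallest p that were lower in LOW RFI were led by GPX3, the plasma glutathione peroxidase that removes peroxides. GPX3 was at 8.32 ± 4.99 RPKM (SD, n = 22) in LOW RFI and 19.5 ± 12.2 RPKM (SD, n = 17) in HIGH RFI cows, a log2 difference of -1.01 (SE 0.29, limma unadjusted p = 0.00105, adjusted 0.769). In 21 of 22 LOW RFI cows it lay below the HIGH RFI median. GPX3 was picked for its small p in these same cows, and the 10 genes picked so had 20 to 22 such cows. The count is therefore no further support. With the month tag as a factor the difference of GPX3 was -0.63 (limma unadjusted p = 0.0935). IFIT1, an interferon-induced inhibitor of viral translation, was at 5.58 ± 7.62 RPKM (SD, n = 22) and 24.1 ± 39.7 RPKM (SD, n = 17), a log2 difference of -1.44 (SE 0.45). Without HIGH RFI 11, where IFIT1 was at 170.5 RPKM, the HIGH RFI mean was 14.9 ± 12.9 RPKM (SD, n = 16) and the log2 difference -1.21 (SE 0.42, limma unadjusted p = 0.00609). The others were KLHL28 (-0.55), NFAT5 (-0.66), a transcription factor of osmotic stress, NIN (-0.78), a centrosome protein, ATP7A (-0.61), a copper transporter, XRN1 (-0.57), an RNA exonuclease, REV3L (-0.55), a DNA polymerase subunit, gene:ENSBTAG00000000682 (-0.58) and gene:ENSBTAG00000051080 (-0.66). None passed after adjustment, and the 10 had unadjusted p from 0.00105 to 0.00266. Each of the 10 was highest in a HIGH RFI cow. Without that cow the limma unadjusted p ran from 0.00253 (GPX3) to 0.00634 (REV3L). NIN, for example, was at -0.62 (SE 0.20) without HIGH RFI 11.

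Genes with the smallest p that were higher in LOW RFI differed by less as deposited. With quantile normalization they were at 0.43 (PLEKHH3) to 0.54 (AACS). The lower ones then were at -0.39 (REV3L) to -0.62 (NIN), apart from GPX3 (-0.84) and IFIT1 (-1.29). NOXA1, an activator of NADPH oxidase, was at 1.65 ± 0.561 RPKM (SD, n = 22) in LOW RFI and 1.09 ± 0.558 RPKM (SD, n = 17) in HIGH RFI cows, a log2 difference of 0.36 (SE 0.12, limma unadjusted p = 0.00334). MVK, mevalonate kinase of cholesterol synthesis, was at 15.5 ± 3.79 RPKM (SD, n = 22) and 11.8 ± 3.87 RPKM (SD, n = 17), a log2 difference of 0.40 (SE 0.14). AACS, which activates acetoacetate for lipid synthesis, differed by 0.40. IQANK1 (0.43), PLEKHH3 (0.32), PTOV1 (0.34), FGFRL1 (0.34), SCRN2 (0.30), C10H15orf62 (0.30) and RNF208 (0.35) made up the rest. The largest unadjusted p of these 10 was 0.0218, and all had an adjusted p of 0.769.

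Interferon response genes were the immune group with the most members at small p. Of 41 tested members, 40 were lower in LOW RFI, with a median log2 difference of -0.53 (-0.41 relative to all genes), and 13 had an unadjusted p under 0.05, but none passed over all genes or adjusted over the list alone. With quantile normalization 5 members passed over the list alone (IFIT1, PARP14 and IFIH1 at an adjusted p of 0.0377, EIF2AK2 and IFIT5 at 0.0445), which were named after their values were seen, and 0 did with rescaling. ISG15, a ubiquitin-like protein, was at 82.4 ± 80.2 RPKM (SD, n = 22) and 193.4 ± 206.9 RPKM (SD, n = 17), a log2 difference of -0.95 (SE 0.48). Without HIGH RFI 11, where ISG15 was at 808.8 RPKM, the log2 difference was -0.77 (SE 0.47, limma unadjusted p = 0.109). camera called the list lower (adjusted p = 2.60e-09), and the adjusted p was 0.626 with an estimated correlation. fry, which asks whether the genes move one way on balance, gave p = 0.0463 unadjusted and 0.444 adjusted. As a score per cow, the list differed by -0.56 (permutation p = 0.0438, adjusted over the lists 0.441), and 19 of 22 LOW RFI cows lay below the HIGH RFI median. The cell cycle score and the growth hormone, insulin and mTOR signalling score also had 19 of 22. This count therefore does not set apart the interferon response score. Within months the score differed by -0.79 in September 2019 (exact permutation p = 0.267), by 0.27 in January 2020 (exact p = 1) and by 0.22 in June 2020 (exact p = 0.774). Its direction turned in January, with 2 cows against 2, and in June. In June HIGH RFI 14 and HIGH RFI 16, at 3.37 and 3.62, lay above the LOW RFI mean of 2.86. HIGH RFI 17 was at 0.912, so the June turn rests on 1 cow. LOW RFI 20, also in June, was at 1.26. The list's median was -0.27 with month as a factor, and -0.14 and -0.15 with the smaller and larger sets of cell type scores as covariates. The neutrophil score differed by -0.86.

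Other immune lists were lower in LOW RFI in nearly every member, with no member passing. All 16 tested neutrophil genes were lower, with a median of -0.87 (-0.75 relative to all genes), among them CXCR1, a receptor of CXCL8 (-1.46, SE 0.69), and S100A12, a calgranulin (-0.53, SE 0.50). CXCR1 was at -1.19 (SE 0.67) without HIGH RFI 11, its highest cow. S100A12 was at -0.65 (SE 0.49) without its highest cow, LOW RFI 10. Inflammatory cytokine and NF-kB genes were lower in 25 of 26 members (median -0.52, -0.40 relative to all genes), including IL1RN (-1.08, SE 0.56) and NFKBIA (-0.69, SE 0.51). IL1RN and NFKBIA were at -0.85 (SE 0.54) and -0.48 (SE 0.50) without HIGH RFI 11. Antigen presentation class II and dendritic genes were lower in all 18 (median -0.43, -0.32 relative), with CD74 at -0.34 and BOLA-DRA at -0.43, and pattern recognition genes in all 22 (median -0.40, -0.29 relative), or 18 of 22 with quantile normalization, with CD14 at -0.46 and MYD88 at -0.36. camera called these 4 lists lower, with adjusted p of 3.92e-05, 0.00673, 0.00124 and 0.00124. With an estimated correlation the adjusted p were 0.748, 0.873, 0.873 and 0.873. With cell type scores as covariates camera called the inflammatory list in the opposite direction, higher in LOW RFI (adjusted p = 0.00174 with epithelium and neutrophil scores, 0.00220 with macrophage and T cell scores added), and called neither the class II nor the pattern recognition list, while the neutrophil list cannot be tested beside its own score. These calls used the preset correlation. With an estimated correlation camera called 0 lists in the 2 covariate fits, with smallest adjusted p over all lists of 0.982 and 0.611. With the month tag as a factor none of the 4 was called, and S100A12, NFKBIA, CD74, BOLA-DRA and MYD88 turned to 0.025, 0.029, 0.15, 0.11 and 0.11. In the months that hold both groups camera called the neutrophil, class II and pattern recognition lists lower (adjusted p = 0.00457, 0.0197 and 0.0304). The inflammatory list was not called there (0.189). With an estimated correlation 0 lists were called in either fit.

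Macrophage genes were lower in all 19 tested members (median -0.40, -0.29 relative to all genes, camera adjusted p = 0.138), with CTSD at -0.37 and APOE at -0.15. Antigen presentation class I genes were lower in all 15 (median -0.33, -0.22 relative, adjusted p = 0.0749), with BOLA at -0.33 and JSP.1 at -0.40. Acute phase and antimicrobial genes were lower in 14 of 16 (median -0.51, -0.39 relative, adjusted p = 0.0785), with LYZ at -0.72 and DEFB4A at -0.56. Complement and Fc receptor genes were lower in 17 of 21 (median -0.39, -0.27 relative, adjusted p = 0.138), with FCER1G at -0.55 and ITGB2 at -0.39. camera called the macrophage, class I, acute phase and complement lists lower with quantile normalization (adjusted p = 0.00816, 0.00816, 0.0116 and 0.00816) and with rescaling (0.0192, 0.0117, 0.0186 and 0.0192), and with an estimated correlation it called 0 lists under either scaling. NK and cytotoxic genes were lower in 10 of 11 (median -0.34, -0.23 relative, adjusted p = 0.257), with NKG7 at -0.39 and CTSW at 0.28, or 0.12 without LOW RFI 12. B and plasma cell genes were lower in all 7 (median -0.28, -0.17 relative, adjusted p = 0.199), with DERL3 at -0.19 and CD79A at -0.073, which turned to 0.090 with quantile normalization and 0.042 with rescaling. T cell genes were lower in 17 of 22, with a median of -0.15 (-0.030 relative) and a mean of -0.17 (-0.057 relative), while camera gave the direction as higher (adjusted p = 0.940), so these differ in sign, and CD3E and CD3D were at 0.046 and 0.021, or -0.066 and -0.10 without LOW RFI 12. With the month tag as a factor CTSD, APOE, BOLA, JSP.1 and CD79A turned to 0.046, 0.15, 0.049, 0.42 and 0.16.

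Cell cycle genes were lower in all 25 tested members, with a median of -0.36 (-0.25 relative to all genes). PCNA, the DNA polymerase clamp, differed by -0.18 (SE 0.21) and MCM7, a replicative helicase subunit, by -0.13 (SE 0.23). camera called the list lower (adjusted p = 1.44e-04), and the adjusted p was 0.873 with an estimated correlation. With the month tag as a factor PCNA and MCM7 turned to 0.037 and 0.053, and in the months that hold both groups to 0.058 and 0.13. The list's median stayed lower in these fits, at -0.20 and -0.13. camera with the preset correlation called the list lower in both (adjusted p = 2.32e-04 and 8.18e-04), and with an estimated correlation it called 0 lists in either. The list's score rose with the macrophage score across the cows (Pearson r = 0.85, Spearman rho = 0.77, each at permutation p = 1e-05, the smallest that 100000 permutations can give, adjusted 2.08e-05 and 3.38e-05), and the macrophage score differed by -0.42 between the groups. The r was 0.78 without the 2 cows farthest from the median macrophage score, and 0.67, 0.77 and 0.92 in September 2019, February 2020 and June 2020, the months with at least 6 cows. It was picked after the relations of the cell cycle score with all 27 other lists had been seen, of which 24 had an adjusted p of r under 0.05. Fatty acid oxidation (r = 0.91) and proteasome (r = 0.87) scores ranked above macrophage, and milk protein ran the other way (r = -0.67). With epithelium, neutrophil, macrophage and T cell scores as covariates the list's median was -0.28 and camera with the preset correlation called it lower (adjusted p = 9.32e-13). With an estimated correlation that fit called 0 lists, and the smallest adjusted p of any list was 0.611.

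Genes of milk and lipid synthesis and of the ribosome tended to lie on the other side, higher in LOW RFI, again with no member passing. Milk protein genes were higher in all 14 members (median 0.80, 0.92 relative to all genes), mammary epithelium genes in 13 of 15 (median 0.18, 0.30 relative), with KRT19 at 0.39 and KRT7 at 0.18, and milk fat synthesis genes in 18 of 22 (median 0.13, 0.24 relative), with FABP3, a fatty acid binding protein, at 0.71 (SE 0.62) and PLIN2, a lipid droplet coat protein, at 0.11 (SE 0.13). Cholesterol synthesis and uptake genes were higher in 19 of 23 (median 0.20, 0.32 relative to all genes), with FDFT1, squalene synthase, at 0.29 (SE 0.21) and INSIG1, a regulator of sterol sensing, at 0.34 (SE 0.20). Cytosolic ribosome genes were higher in 76 of 77 (median 0.20, 0.31 relative), with RPLP1 at 0.26 and RPLP0 at 0.16. camera called these 5 lists higher, with adjusted p of 2.60e-09, 3.92e-05, 1.90e-06, 2.60e-09 and 2.19e-28. With an estimated correlation the adjusted p were 0.465, 0.558, 0.0933, 0.465 and 0.465. With epithelium and neutrophil scores as covariates camera did not call the milk protein and milk fat synthesis lists (adjusted p = 0.739 and 0.680), and the mammary epithelium list cannot be tested beside its own score. With the month tag as a factor camera called the milk protein and milk fat synthesis lists higher (adjusted p = 0.0168 and 0.0462) and not the mammary epithelium list (0.210). In the months that hold both groups none of the milk protein, mammary epithelium and milk fat synthesis lists was called (adjusted p = 0.587, 0.162 and 0.207). With an estimated correlation 0 lists were called in either fit. Without the libraries that carry the mark, the milk protein and mammary epithelium lists were not called either (adjusted p = 0.0554 and 0.187). The cholesterol synthesis and uptake score differed by 0.32, 0.25 and 0.21 in September 2019, January 2020 and June 2020 (exact permutation p = 0.4, 0.333 and 0.607), and by 0.22 adjusted for all months. The June value leans on HIGH RFI 17, at 3.57, as HIGH RFI 14 and HIGH RFI 16 were at 4.76 and 4.43 and the LOW RFI mean was 4.46.

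**Figure D3:**
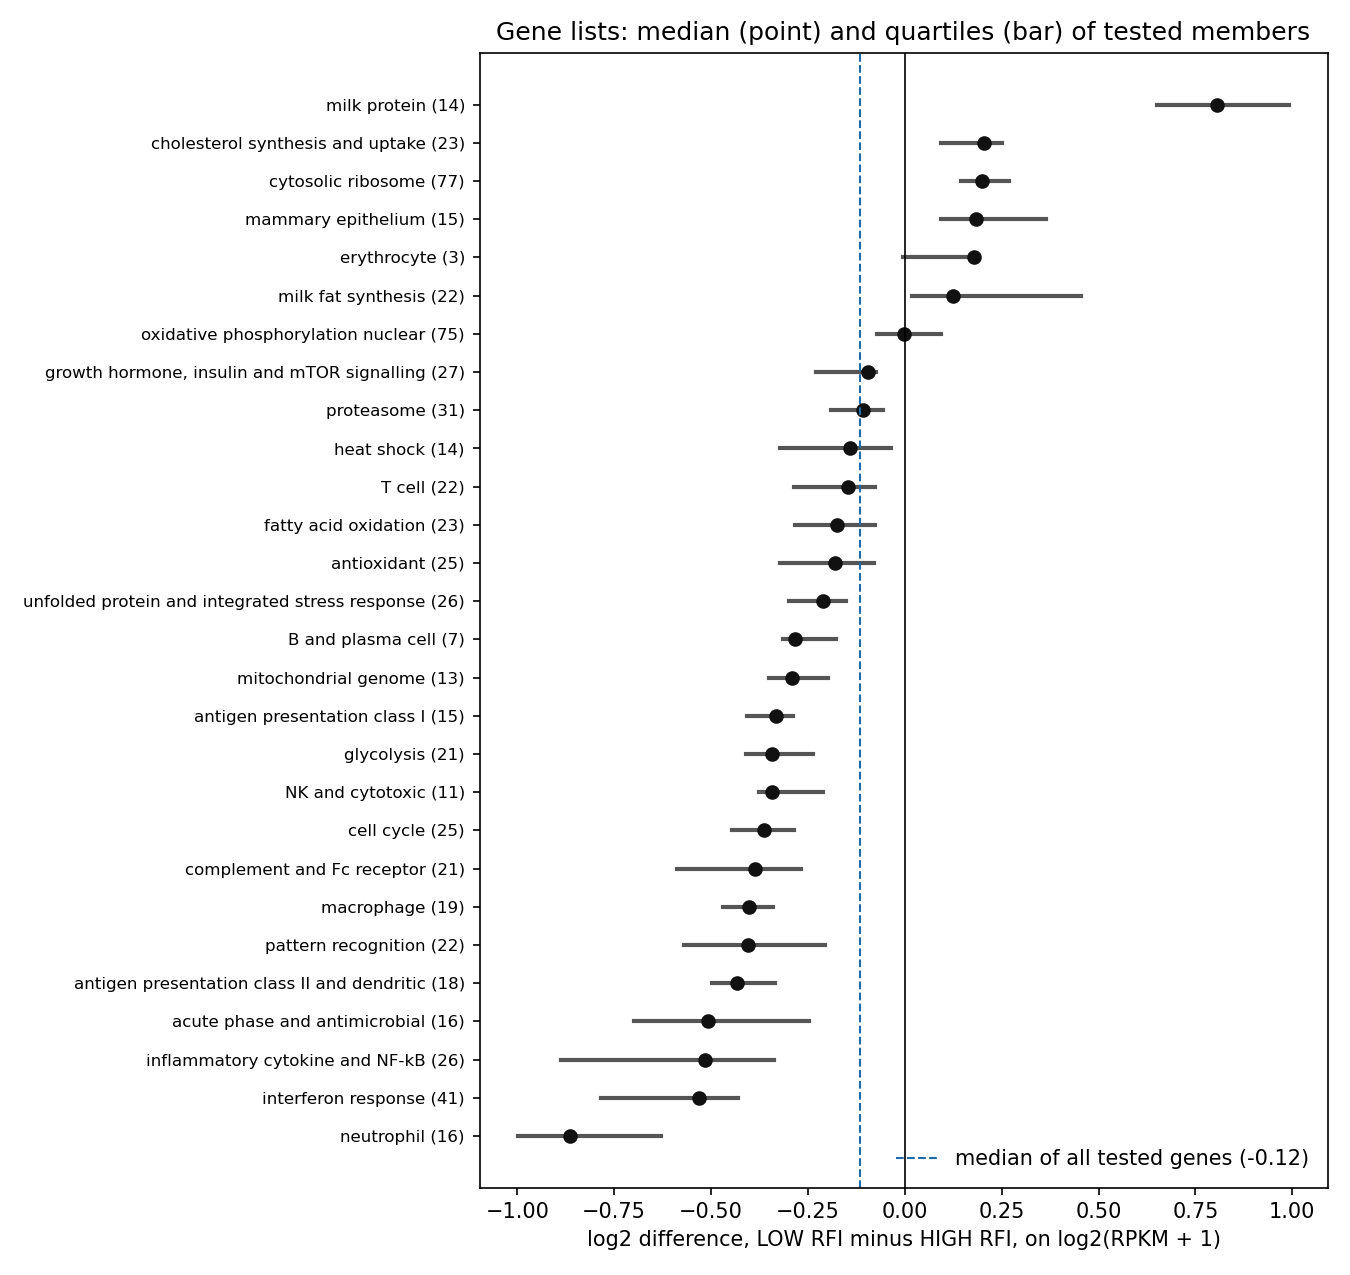
Median log2 difference, LOW RFI minus HIGH RFI (x axis), of the tested members of each of 28 gene lists (y axis, number of tested members in brackets), with bars from the first to the third quartile and a dashed line at the median of all genes, -0.12. The neutrophil list lies lowest at -0.87 and the milk protein list highest at 0.80, and no member of any list passed over all genes.

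No member of the energy and stress lists passed over all genes. Nuclear genes of oxidative phosphorylation had 37 members higher and 38 lower, and their median of -0.0020 and mean of 0.0025 differed in sign. camera called this list higher (adjusted p = 4.39e-04), relative to all genes (relative median 0.11), and its adjusted p was 0.873 with an estimated correlation and 0.9805 with the month tag as a factor, while its median turned to 0.15 with quantile normalization and 0.10 with rescaling. ATP5MG was at 0.11, and COX4I1 was at -0.062, which turned to 0.079 and 0.045 under the same scalings. The 13 mitochondrial genome transcripts were all lower (median -0.29, -0.18 relative, camera adjusted p = 0.201), with COX1 at -0.30 and COX3 at -0.20, and camera called the list lower with quantile normalization (0.0116) and rescaling (0.0419). Glycolysis genes were lower in 19 of 21 (median -0.34, -0.23 relative, adjusted p = 0.311, or 0.0290 with quantile normalization and 0.0601 with rescaling), with GAPDH at -0.33 and ENO1 at -0.40, and fatty acid oxidation genes in 19 of 23, or 12 of 23 with quantile normalization (median -0.17, -0.058 relative, adjusted p = 0.625), with ACADVL at -0.22 and ACAA1 at -0.15, which was 0.00051 with quantile normalization. With the month tag as a factor GAPDH, ENO1, ACADVL and ACAA1 turned to 0.018, 0.011, 0.017 and 0.13.

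As deposited, 1 of the 668 tested members passed when adjusted over its list alone, and with quantile normalization 5 interferon response genes did too. That member was GPX3, of the antioxidant list (adjusted p over the list alone = 0.0262), which did not pass over all genes. Of the 25 tested antioxidant genes 22 were lower, or 16 with quantile normalization (median -0.18, -0.066 relative, camera adjusted p = 0.432), with GPX1 at -0.37 and PRDX1 at -0.27. Growth hormone, insulin and mTOR signalling genes were lower in 22 of 27, or 10 of 27 with quantile normalization, with a median of -0.095 (0.020 relative) that turned to 0.040 with quantile normalization (camera adjusted p = 0.454), with EIF4EBP1 at 0.19 and AKT1 at -0.083, which turned to 0.085 with quantile normalization and 0.023 with rescaling. Unfolded protein and integrated stress response genes were lower in 25 of 26, or 19 of 26 with quantile normalization (median -0.21, -0.096 relative, adjusted p = 0.220), with ATF4 at -0.20 and HSPA5 at -0.16, which was 0.019 with quantile normalization. Heat shock genes were lower in 11 of 14, or 7 of 14 with quantile normalization (median -0.14, -0.025 relative, adjusted p = 0.632), with HSPA8 at -0.16 and HSPB1 at -0.028, which turned to 0.070 with quantile normalization and 0.078 with rescaling. Proteasome genes were lower in 28 of 31, or 11 of 31 with quantile normalization, with a median of -0.11 (0.0062 relative) that turned to 0.047 with quantile normalization (adjusted p = 0.642), with PSMA7 at -0.095 (0.072 with quantile normalization, 0.011 with rescaling) and PSMB1 at -0.12 (0.047 with quantile normalization). With the month tag as a factor AKT1, ATF4, HSPA5, HSPB1 and HSPA8 turned to 0.13, 0.043, 0.010, 0.19 and 0.20. Of the erythrocyte list 3 members were tested, too few for camera, with SLC25A37 at 0.19 and HBA at -0.19, which turned to 0.22 with the month tag.

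In total camera called 12 of 27 lists with the preset correlation, 6 higher and 6 lower, and 0 with an estimated correlation. fry called 0, with a smallest adjusted p of 0.444. Of the 12, 4 (interferon response, cytosolic ribosome, cholesterol synthesis and uptake, and cell cycle) were called in the same direction with the preset correlation in all 21 other fits, and 8 were not called or turned direction in at least 1, which for the epithelium and neutrophil lists includes fits with their own scores. With an estimated correlation 3 of those fits called 1 list, milk fat synthesis, higher (adjusted p = 0.0471 with the stricter filter, 0.0134 with library number as a covariate and 0.0496 with limma-voom without quality weights).

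RPL12, a protein of the large ribosomal subunit, did not follow the rest of its list and was chosen after its values were seen. It was below 1 RPKM in 20 cows, 9 of 22 LOW RFI and 11 of 17 HIGH RFI (Fisher's exact p = 0.200), and between 300.6 and 1192 RPKM in the other 19. The feature gene:ENSBTAG00000025385 was at 1075 ± 462 RPKM (SD, n = 39). As a share of the reads of both features, RPL12 took 0.00603% to 0.0450% in 20 cows, 36.5% to 38.0% in 16 cows and 71.9% to 75.9% in 3 cows, with no cow between.

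**Figure D4:**
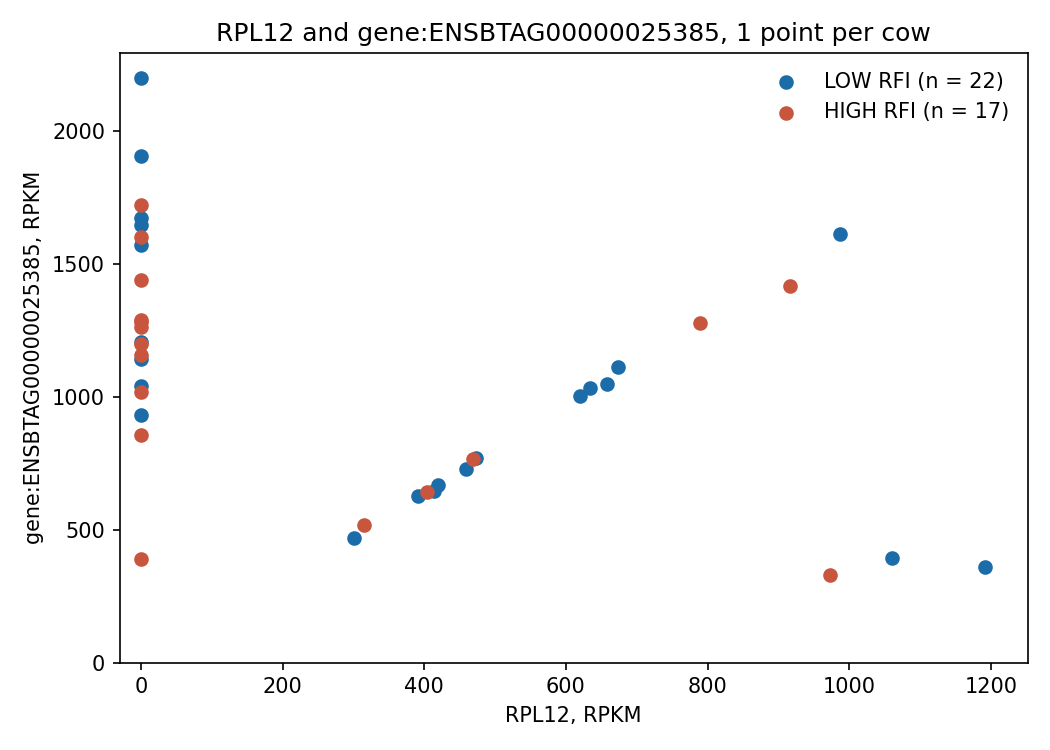
RPKM of RPL12 (x axis) and of gene:ENSBTAG00000025385 (y axis), with 1 point per cow, 22 LOW RFI cows in blue and 17 HIGH RFI cows in red. The points form 3 sets, 20 cows with RPL12 below 1 RPKM, 16 cows along a line where RPL12 takes 36.5% to 38.0% of the reads of both features, and 3 cows at lower right where it takes 71.9% to 75.9%.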

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

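The fits with month tags, marked libraries, residual components, array weights, a length trend, centred libraries or limma-voom without quality weights were chosen after seeing the data, and the other alternatives before. The count of genes at an adjusted p under 0.05 stayed at 0 in every alternative except 3, which gave 1932 (limma-voom with quality weights), 1823 (2 residual principal components) and 2213 (array weights), with 1924 and 866 of the 1932 genes shared with the last and the middle fit. Genes at an unadjusted p under 0.05, 633 in the main test, ranged from 7 (months that hold both groups) and 9 (month tag as a factor) to 3773 (array weights). Those over 1.5 times away from the main count were also 1270 without a filter, 283 with the stricter filter, 307 and 1010 with the smaller and larger sets of cell type covariates, 975 with library number, 1048 without the 4 distant libraries, 349 and 952 with pseudocounts of 0.1 and 5, 106 without marked libraries, 3649 with residual components, 967 with the length trend removed, and 3428 and 225 with limma-voom with and without quality weights. camera called 12 lists in the main test, 5 with either set of cell type covariates, 7 with the month tag as a factor, 0 with an estimated correlation, 0 with fry and 8 to 18 elsewhere. With an estimated correlation, milk fat synthesis alone was called, and only with the stricter filter (adjusted p = 0.0471), library number (0.0134) and limma-voom without quality weights (0.0496). None of the 8 cell type scores passed under any alternative. Of 1643 comparisons of a named gene with its main value, 141 turned direction, as did 56 of 618 for lists and 4 of 71 for scores. In 64 a gene came to pass. A list came to be called in 40, 1 of them with a turn of direction, and lost its call in 61, 6 of them with a turn. Lists whose own score is a covariate lose theirs by construction. Planned for a table of counts, and not run because the deposited unit was RPKM, were DESeq2, size factors from it or from edgeR, and surrogate variables. No paired analysis was possible because replicate numbers only name the cows. No test thinned the reads, so how far depth limits the calls was not tested. Without the shallowest library, of 41637742 mapped reads, 0 genes were called and 501 had an unadjusted p under 0.05. In simulations at these cow numbers limma-trend recovered 21.8% of changes of 0.5 log2, 78.8% of 1 and 98.6% of 2. These shares are for randomly drawn genes changed together. They do not give the recovery of genes with a large SE, as IFIT1 (0.45), CXCR1 (0.69) or CSN2 (0.77). Why results changed between alternatives was not tested, except in the fits that called many genes. The weighted fits were refitted with the month tag and with other splits, and the fit with residual components with other splits. Tests of the lean of small p values and of the limma-trend and camera counts are given further below.

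The values that turned direction are given as log2 differences for genes and scores, and as camera's adjusted p in brackets for lists whose direction turned. With quantile normalization, genes turned to 0.090 for CD79A, 0.079 for COX4I1, 0.019 for HSPA5, 0.070 for HSPB1, 0.00051 for ACAA1, 0.085 for AKT1, 0.072 for PSMA7 and 0.047 for PSMB1. T cell (0.404) and proteasome (0.497) turned among the lists. Without the filter on low values, T cell (0.552) turned among the lists. With libraries rescaled without the milk protein list, genes turned to 0.042 for CD79A, 0.045 for COX4I1, 0.078 for HSPB1, 0.023 for AKT1 and 0.011 for PSMA7. T cell (0.697) and proteasome (0.817) turned among the lists. With epithelium and neutrophil scores as covariates, genes turned to -0.10 for KRT19, -0.019 for KRT7, 0.28 for S100A12, 0.22 for CTSD, 0.33 for APOE, 0.064 for NKG7, 0.32 for CD74, 0.28 for BOLA-DRA, 0.15 for BOLA and 0.048 for JSP.1. NFKBIA was at 0.26, LYZ at 0.035, CD14 at 0.18, MYD88 at 0.18, ATF4 at 0.055, HSPA5 at 0.16, HSPB1 at 0.17, HSPA8 at 0.21, PRDX1 at 0.057 and GAPDH at 0.099. ENO1 was at 0.074, ACADVL at 0.12, ACAA1 at 0.11, AKT1 at 0.11, HBA at 0.043, PSMA7 at 0.036, FCER1G at 0.26, ITGB2 at 0.14 and CSN3 at -0.042. Macrophage (0.546), T cell (0.151), antigen presentation class I (0.703), inflammatory cytokine and NF-kB (0.00174) and pattern recognition (0.906) turned among the lists. Unfolded protein and integrated stress response (0.649), heat shock (0.906), glycolysis (0.0769) and complement and Fc receptor (0.906) turned among the lists. With macrophage and T cell scores added to those covariates, genes turned to -0.048 for KRT19, -0.047 for KRT7, 0.19 for S100A12, 0.079 for CTSD, 0.15 for APOE, 0.25 for CD74, 0.23 for BOLA-DRA, 0.17 for BOLA, 0.070 for JSP.1 and 0.21 for NFKBIA. CD14 was at 0.086, MYD88 at 0.15, ATF4 at 0.067, HSPA5 at 0.090, HSPB1 at 0.11, HSPA8 at 0.18, GAPDH at 0.027, ENO1 at 0.00058, ACADVL at 0.027 and ACAA1 at 0.058. AKT1 was at 0.099, HBA at 0.038, PSMA7 at 0.016, FCER1G at 0.17 and ITGB2 at 0.063. Neutrophil (0.826), macrophage (0.826), antigen presentation class I (0.336), inflammatory cytokine and NF-kB (0.00220) and unfolded protein and integrated stress response (0.826) turned among the lists. Heat shock (0.849), glycolysis (0.244) and complement and Fc receptor (0.826) turned among the lists. With library number as a covariate, genes turned to -0.042 for KRT7, -0.26 for CD3E and -0.27 for CD3D. T cell (0.123) and fatty acid oxidation (0.933) turned among the lists. Without the shallow library LOW RFI 14, T cell (0.822) turned among the lists. Without the 4 distant libraries, genes turned to -0.12 for CD3E and -0.17 for CD3D. T cell (0.702) turned among the lists. At a pseudocount of 5, genes turned to -0.025 for CD3D. T cell (0.663) turned among the lists. With limma-voom and quality weights, genes turned to -0.28 for KRT7, -0.38 for CD3E, -0.42 for CD3D and -0.080 for CTSW. T cell (0.294), inflammatory cytokine and NF-kB (0.200), acute phase and antimicrobial (0.657), unfolded protein and integrated stress response (0.624) and antioxidant (0.657) turned among the lists. Glycolysis (0.8997) turned among the lists. Using the month tag as a factor, genes turned to 0.025 for S100A12, 0.046 for CTSD, 0.15 for APOE, 0.16 for CD79A, 0.15 for CD74, 0.11 for BOLA-DRA, 0.049 for BOLA, 0.42 for JSP.1, 0.029 for NFKBIA and 0.11 for MYD88. ATF4 was at 0.043, HSPA5 at 0.010, HSPB1 at 0.19, HSPA8 at 0.20, GAPDH at 0.018, ENO1 at 0.011, ACADVL at 0.017, ACAA1 at 0.13, AKT1 at 0.13 and MCM7 at 0.053. PCNA was at 0.037 and HBA at 0.22. T cell (0.844), antigen presentation class I (0.844), inflammatory cytokine and NF-kB (0.873), heat shock (0.0967) and glycolysis (0.391) turned among the lists. MTOR signalling (0.956) turned among the lists. In the months that hold both groups, genes turned to 0.16 for CTSD, 0.33 for APOE, 0.17 for CD79A, 0.19 for CD74, 0.12 for BOLA-DRA, 0.098 for BOLA, 0.45 for JSP.1, 0.054 for MYD88, 0.049 for COX4I1 and 0.0037 for ATF4. HSPA5 was at 0.10, HSPB1 at 0.28, HSPA8 at 0.24, GAPDH at 0.093, ENO1 at 0.073, ACADVL at 0.10, ACAA1 at 0.16, AKT1 at 0.14, MCM7 at 0.13 and PCNA at 0.058. HBA was at 0.28, PSMA7 at 0.0048, FCER1G at 0.015 and ITGB2 at 0.0070. T cell (0.702), oxidative phosphorylation nuclear (0.944), heat shock (0.0480), glycolysis (0.587) and proteasome (0.889) turned among the lists. The macrophage score and the T cell score turned to 0.025 and 0.015. Leaving out the marked libraries, genes turned to 0.15 for APOE, 0.068 for CD74, 0.012 for HSPA5 and 0.082 for HSPB1. Macrophage (0.972) and T cell (0.743) turned among the lists. With limma array weights, genes turned to -0.24 for KRT7, -0.35 for CD3E, -0.38 for CD3D and -0.048 for CTSW. T cell (0.277), inflammatory cytokine and NF-kB (0.266), acute phase and antimicrobial (0.601), unfolded protein and integrated stress response (0.741) and antioxidant (0.722) turned among the lists. Removing the gene length trend, genes turned to 0.056 for CD79A, 0.011 for COX4I1, 0.023 for HSPB1, 0.028 for AKT1 and 0.013 for MCM7. T cell (0.401) and mTOR signalling (0.959) turned among the lists. Centring each library, genes turned to 0.046 for CD79A, 0.057 for COX4I1, 0.091 for HSPB1, 0.036 for AKT1 and 0.024 for PSMA7. T cell (0.464) and proteasome (0.784) turned among the lists. Under fry, T cell (0.615) turned among the lists. For scores as medians, the erythrocyte score turned to -0.084. Within library numbers 1 to 20, the erythrocyte score turned to -0.098.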

Other observations

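Chosen only after results were seen were the correlations, the relative scores, the tests of RPL12 and of the lean of small p values, the split by year, the splits of the limma-trend and camera counts, and the fits with month tags, array weights and residual components. The cell type scores moved together across the 39 cows. Cows with high milk protein scores had low macrophage scores (Pearson r = -0.74, Spearman rho = -0.86), with r = -0.74 without the 2 cows farthest from the median milk protein score, -0.76 in the 22 LOW RFI and -0.69 in the 17 HIGH RFI cows. In the months of at least 6 cows, r was -0.81 in September 2019 (6 cows), -0.79 in February 2020 (6 cows) and -0.80 in June 2020 (9 cows). T cell and NK and cytotoxic scores rose together (r = 0.94, rho = 0.92, and r = 0.92 without the 2 farthest cows), with r of 0.87, 0.91 and 0.97 in those months. For both relations the permutation p of r and of rho was 1e-05, the smallest that 100000 permutations can give, with adjusted p of 5.6e-05 and 7e-05 over the 28 relations computed, of which 16 had an adjusted p of r and 10 an adjusted p of rho under 0.05. Some rested on the 2 farthest cows, as macrophage with NK and cytotoxic scores, where r fell from 0.41 to 0.071 without them. Neutrophil and macrophage scores had r = 0.71 (permutation p = 1e-05, adjusted 5.6e-05) and rho = 0.66 (p = 3e-05, adjusted 1.4e-04), with r = 0.68 without the 2 farthest cows, but r of 0.87, 0.089 and 0.80 in the months, so that relation did not hold in February 2020. Scores come from shares of the same library, so a rise of 1 abundant list lowers the others by construction.

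HIGH RFI 11 held the highest value in 48 of the 60 genes with the widest gap below their highest cow. In it BIRC3, an inhibitor of apoptosis, was at 641 RPKM against 105.5 in the next cow and a median of 24.1, and SAMSN1 was at 455.6 against 86.4. Other features had an empty interval between cows, as RPL12 did. The feature gene:ENSBTAG00000053198 was at or below 2.56 RPKM in 21 cows and at or above 235.7 in 18, and gene:ENSBTAG00000006383 at or below 1.53 in 17 and at or above 40.1 in 22. GSTO1, a glutathione transferase, was at or below 0.0459 RPKM in 13 cows and at or above 2.11 in 26. Relative to the mean of all genes, the interferon response score differed by -0.43 between the groups (permutation p = 0.0219) and the cholesterol synthesis and uptake score by 0.30 (p = 0.0246), and neither passed over the lists (adjusted p = 0.344).

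RPL12 was near 0 in 20 cows and abundant in the other 19. Low RNA quality or depth of those libraries is argued against, since 0 of the other 76 tested ribosomal genes ranged over 100-fold between cows. Reads shared with gene:ENSBTAG00000025385 remain a candidate explanation, because the variance of the sum of both was 0.573 of the sum of their variances, the lowest among 248 features of like variance (p = 0.0352 over shuffles of the cows). An inherited variant that moves reads between RPL12 and gene:ENSBTAG00000025385 may set the share, as the median shares of 0.0214%, 37.1% and 73.7% in 20, 16 and 3 cows are evenly spaced, and Hardy-Weinberg proportions predict 20.1, 15.8 and 3.10 cows (exact p = 1, which does not show that the proportions hold). Neither sequence nor genotype was tested, so this stays a hypothesis.

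Of the 633 genes at an unadjusted p under 0.05, 587 were lower in LOW RFI. Among 100 splits of the cows into groups of 22 and 17, the real one included, 20 gave as many in one direction and the highest other gave 4168, so chance cannot be excluded, and counts several times the real one point to a structure of the samples. The split by year in the column names, 17 cows of 2019 against 22 of 2020, gave 1740 genes, 1732 of them lower in 2020. The year 2019 held 13 LOW RFI and 4 HIGH RFI cows, and 2020 held 9 and 13. Lower values in 2020 would thus lower HIGH RFI, so a year difference in that direction would not give the lean of the 587 genes. However, the year difference was not computed for those genes, and no fit held year and RFI group together. A split by year also does not test single months. With the month tag as a factor the comparison of LOW RFI with HIGH RFI gave 9. That comparison rests on the months that hold both groups, with 19 LOW RFI and 9 HIGH RFI cows. The fall to 9 therefore cannot be told apart from a loss of cows. Milk protein transcripts taking reads from all other genes stay open, since the share lower in LOW RFI was 66.2% after rescaling without the milk protein list, and 75 of the 100 splits had a share that high in their commoner direction after the same rescaling. A gene length trend cannot be told apart from a plain shift between libraries, since the share was 45.7% with the trend removed and 52.6% with libraries only centred.

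Limma-trend called 0 genes, as did every one of the 100 splits, while 3 other fits called many. Limma-voom with quality weights called 1932 (8 of 100 splits called as many, the highest other 5743), array weights 2213 (9 of 100, highest other 6473) and 2 residual components 1823 (30 of 100, highest other 6292), so chance cannot be excluded for any of them, and splits with several times the real count point to a structure of the samples. For the 12 lists of camera, 62 of 100 splits called as many and the highest other 20, so chance cannot be excluded there either. Month tags that differ between the groups may contribute, since limma-voom with quality weights and the month tag as a factor called 0. Array weights with the month tag also called 0. However, such a fit spends more degrees of freedom and compares only 19 LOW RFI with 9 HIGH RFI cows, those of the months that hold both groups. The split by year alone also called 0. For limma-trend the count of 100 splits matching its 0, with a highest other of 0, excludes nothing, and a difference in biology between the RFI groups stays open as untested.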
